A study of Homo sapiens with 5 samples.

How the data were processed

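The series measured binding of IRF3 and Smad3 by ChIP-seq in BT549 cells that stably carried an HA control vector or constitutively active Smad3 (caSmad3) from lentiviral vectors, per the labels' protocols. Chromatin was precipitated with an anti-IRF3 or anti-Smad3 antibody, and libraries were made with a fragment library kit for Ion sequencers and amplified by 15 cycles of PCR, per the labels' protocols. The genome build hg38, Bowtie2 2.2.2.6 and MACS2 2.1.0 are named in the submitters' processing notes. The thresholds of peak calling, the use of an input control and the treatment of duplicate reads are not given in the sources used here.

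The authors deposited 1 peak list for each of the 5 libraries, with a chromosome, a start, an end and a peak name for each peak. The deposited values used here are therefore positions in bases, with no score, fold enrichment, p-value or read count. Each list was made from 1 sample, and peaks were not pooled across libraries, as each list belongs to its own sample. Peak numbers in the names ran beyond the number of peaks by 63, 93, 43, 44 and 62 in the order IRF3 in HA cells, IRF3 in caSmad3 cells, Smad3 after mock transfection, Smad3 after polyI:C and Smad3 in caSmad3 cells, with 0 gaps inside a chromosome. The narrowest peak was 99 bases in each list, and 7.71% to 10.8% of peaks had that width. Sequencing depth is unknown, so list length may not be read as strength of binding. Precision is given by the number of peaks or genes behind each share, or as a 95% Clopper-Pearson interval. A count of 0 genes of a list within 10 kb is given with the share that 3 counts would make. PCR reads are not independent molecules, so these limits cover counting error only.

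Groups were taken from the labels and each holds 1 library, so no test was made between conditions. The comparison of Smad3 between HA and caSmad3 cells joins the effect of caSmad3 with the lack of TGF-beta, because HA cells had received TGF-beta and caSmad3 cells had not. Peaks were called shared when they had at least 1 base in common. Chance overlap was measured by moving 1 list to random positions on the same chromosome, within the same class (centre within 1 kb of an end of a protein-coding gene, or not), in 1000 copies with a fixed seed, and the test was one-sided. Moved peaks were not confined to chromatin accessible in these cells. Peak lists of the same cell line can exceed such copies for that reason alone, so a low p-value is no evidence of joint binding. For 4 comparisons this test was tried on simulated data. Lists with 10% planted overlap were called in 20 of 20 copies, and the planted overlap came back at 96.2% to 99.9% of its size. Random lists, made by the same moves as the test itself, were called in 0 or 1 of 20 copies. These trials used fewer than 1000 moved copies per test and planted peaks at exact positions of the other list. They check the procedure, and not whether moved copies suit real peaks.

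Genes came from a RefSeq table of assembly GRCh38.p14, which has the coordinates of hg38, with 20033 protein-coding genes. The table used here gives the lower and upper position of each gene and no strand, so distances were measured to the nearer gene end, where transcript starts had been planned. A position called below or above a gene refers to lower or higher coordinates, not to the direction of transcription. Exons, introns and UTRs were not used here, and neither was the genome sequence, so the planned search for 14 motifs was not run.

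Before the data were examined, 14 gene lists with 396 genes were fixed, all of which matched the table. They are direct IRF3 targets, interferon-stimulated genes, antigen presentation, RNA sensing and IRF3 activation, NF-kB and inflammatory genes, cell death, TGF-beta/Smad targets, TGF-beta pathway components, mesenchymal and matrix genes, AP-1 and immediate early genes, epithelial and luminal markers, leukocyte markers, housekeeping genes and silent tissue-specific genes. A gene counted as bound when a peak lay within 10 kb of either end. Fisher's exact test (two-sided) set list members against all other protein-coding genes in each library, with Benjamini-Hochberg adjustment over the 70 tests. It describes each library alone. In simulations with 200 random lists of 40 genes per library, 4 to 11 were called at an unadjusted threshold of 0.05, and 200 of 200 lists with 24 planted genes were called. Because neighbouring genes can share a peak, the test was repeated after seeing the data with all 20033 rotations of each list along the genes in genomic order (two-sided, adjusted over the 70 tests). With 200 random lists made of runs of 4 neighbouring genes, the exact test called 8 to 23 per library and the rotations 2 to 9, and the rotations called 200 of 200 planted lists.

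Peaks near a list were compared with 10000 draws of as many other peaks of the same library, matched by width in 10 bins. The named-gene rule was fixed in advance as the members of the lists with a peak in at least 1 compared library, at most 4 per list and class, and the nearest genes of the top 3 peaks of each class within 50 kb. IRF3, SMAD3, SMAD7, IFNB1, IFIT1, ISG15, CCL5 and CXCL10 are always reported. Some genes that the rule names are not reported here. The rule ranked by peak score, and as the lists hold none, peak width was used in its place.

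Alternatives planned in advance were a 50% reciprocal overlap, centres within 200 bases, random positions without classes, merged peaks, main chromosomes only, gene-end windows of 2.5 kb, ends of all genes, list windows of 1 kb and 50 kb, and a background of genes with a peak in any library. Those that needed peak scores were not run. In their place, the wider 50% of each list, equal numbers of the widest peaks, and a minimum width of 200 bases were chosen after seeing the data, as were the lists without structural RNA and histone genes, the omission of the IFIT cluster and the rotated lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.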

Results

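The data were ChIP-seq peak lists for the transcription factors IRF3 and Smad3 in BT549 cells, an established line of basal-like breast cancer. IRF3 is activated by sensors of viral RNA and switches on interferon beta, and Smad3 carries the TGF-beta signal from its receptors to the genome. PolyI:C, a synthetic analogue of double-stranded RNA, was transfected to activate IRF3. Cells carried either a control vector (HA) or constitutively active Smad3 (caSmad3). The 5 groups held 1 library each: IRF3 in HA cells and in caSmad3 cells after polyI:C, Smad3 in HA cells given TGF-beta (1 ng/ml for 1.5 h) after mock transfection or polyI:C, and Smad3 in caSmad3 cells after polyI:C without TGF-beta. The lists held 4125 IRF3 peaks in HA cells and 8067 in caSmad3 cells. Smad3 had 353 peaks in mock-transfected HA cells, 786 in HA cells given polyI:C and 6041 in caSmad3 cells. Median widths were 185 and 215 bases for IRF3, and 164, 154.5 and 178 bases for Smad3. Read depth is unknown from such lists, so neither list length nor the absence of a peak measures the amount of binding. With 1 library per group no difference between conditions could be tested, and all 95% Clopper-Pearson intervals below cover counting error only.

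IRF3 peaks lay at gene ends more often than Smad3 peaks, although 31.6% of the Smad3 peaks of caSmad3 cells overlapped an IRF3 peak of the same cells. Within 1 kb of an end of a protein-coding gene lay 75.2% of the IRF3 peaks of HA cells (73.9 to 76.5) and 76.9% of those of caSmad3 cells (75.9 to 77.8). For Smad3 the shares were 13.0% in mock-transfected HA cells (9.70 to 17.0), 21.1% in HA cells given polyI:C (18.3 to 24.1) and 33.1% in caSmad3 cells (31.9 to 34.3). Random positions gave 2.61% to 2.96%. Counting the ends of non-coding genes as well moved the Smad3 share in mock-transfected cells to 41.1% and that in HA cells given polyI:C to 41.2%.

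The first comparison asked where IRF3 was found after polyI:C when active Smad3 was present. Most IRF3 sites of HA cells were also listed in caSmad3 cells, but the classical interferon genes were an exception. IFNB1, which encodes interferon beta, had 6 IRF3 peaks within 10 kb in HA cells and 0 in caSmad3 cells. The antiviral genes IFIT1, IFIT2 and IFIT3 had 5, 8 and 9 peaks in HA cells, and the chemokine gene CCL5 had 1, with 0 for each of these genes in caSmad3 cells. CCN2, a TGF-beta target that encodes connective tissue growth factor, showed the opposite, with 0 peaks in HA cells and 6 in caSmad3 cells. The 6 peaks at CCN2 ran along the whole gene (131947649 to 131951502, gene 131948176 to 131951372). Those at IFIT2 in HA cells did so too (89301792 to 89310067, gene 89302046 to 89309271). Numbers of peaks are therefore not numbers of separate sites. Whether signal along a gene came from IRF3 was not tested, as no input or IgG library was analysed here.

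Of the list of 20 direct IRF3 targets, 12 had an IRF3 peak within 10 kb of a gene end in HA cells and 4 in caSmad3 cells, with 3 genes in common. Those 3 were ISG15, ZC3HAV1, a zinc finger antiviral protein, and PMAIP1, which encodes the pro-apoptotic protein NOXA. At ISG15 the widest peak was 750 bases in HA cells (chromosome 1, 1013056 to 1013805, hg38) and 309 bases in caSmad3 cells (1013279 to 1013587), both over the lower gene end. The widest peaks without a counterpart in caSmad3 cells lay at IFIT2, with 2071 bases (chromosome 10, 89307997 to 89310067) and 1182 bases (89301792 to 89302973), and at CCL5 with 762 bases (chromosome 17, 35879891 to 35880652). All 3 overlapped an end of their gene. The peaks at IFIT1 (chromosome 10, 89392329 to 89392955) and IFIT3 (89327655 to 89328309) also lay over a gene end, and so did 1 of the 6 at IFNB1 (chromosome 9, 21077925 to 21078119). A further 2 of the 6 lay inside IFNB1 (21077284 to 21077439 and 21077502 to 21077788), and the widest (21070030 to 21070383) lay 6721 bases below the gene.

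Interferon-stimulated genes followed the same pattern, with 25 of 47 near an IRF3 peak in HA cells, 11 in caSmad3 cells and 9 in both. RIGI and IFIH1, which encode cytoplasmic RNA sensors, and the neighbouring genes PARP9 and DTX3L had a peak in HA cells and none in caSmad3 cells. TRIM25 and DDX60 had peaks in both, and STAT2 and SOCS1 had one in caSmad3 cells alone. IFI6 and DHX58 counted in both through peaks at different positions. The peak at IFI6 was 511 bases over the gene in HA cells and 215 bases, 5785 bases below it, in caSmad3 cells, and the widest at DHX58 lay over the gene in HA cells and 8641 bases above it in caSmad3 cells. Of 18 antigen presentation genes, 9 had a peak in HA cells, 4 in caSmad3 cells and 2 in both. TAP1, TAP2 and PSMB8 are neighbours whose widest HA peak within 10 kb was the same one (chromosome 6, 32838159 to 32838379), with no counterpart in caSmad3 cells, and the 9 bound genes rest on 8 peaks, whereas B2M and HLA-E had peaks in both. The list of 24 NF-kB and inflammatory genes gave 14, 10 and 8. CXCL1, CXCL2, NFKBIA and RELB had peaks in both lists, and CXCL8, CCL2, NFKBIZ and ICAM1 in HA cells alone.

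Other groups had no fewer bound genes in caSmad3 cells, where the share of all protein-coding genes with a peak was also higher (39.1% against 22.5%). The number with a peak went from 13 to 24 of 40 TGF-beta/Smad target genes, with 11 in both, and from 5 to 14 of 33 mesenchymal and matrix genes, with 5 in both. CCN1, GADD45B, JUNB and KLF10 had IRF3 peaks in both libraries, and CCN2, PMEPA1, SNAI2 and SMAD6 in caSmad3 cells alone. The widest caSmad3-only peak lay over CCN2 with 1203 bases (chromosome 6, 131948061 to 131949263). It was followed by peaks at the gene ends of PLAA (chromosome 9, 26946944 to 26947808) and TTC32 (chromosome 2, 19901564 to 19902318). Cell death genes gave 9 and 17 of 40, with BAX, MCL1, TNFRSF10D and CYCS in both and BCL2L1, MLKL, BAD and XIAP in caSmad3 cells alone. AP-1 and immediate early genes gave 14 and 18 of 26, with the 14 all in both. TGF-beta pathway components gave 5 and 8 of 28, RNA sensing genes 5 and 6 of 19, and housekeeping genes 17 and 21 of 26. In caSmad3 cells the shares of matrix genes (42.4%), cell death genes (42.5%), pathway components (28.6%) and RNA sensing genes (31.6%) did not pass against other genes (Fisher's exact test, adjusted p = 1.0, 1.0, 0.65 and 1.0), and none of the 4 passed in HA cells (0.75, 1.0, 1.0 and 1.0), nor did Smad targets there (32.5%, 0.32). RIPK1 among cell death genes and ANGPTL4 among Smad targets counted in both without a shared peak. The IRF3 gene itself had a peak at its upper end in both libraries. SMAD3 and the interferon-inducible chemokine gene CXCL10 had no peak within 10 kb of a gene end in any of the 5 lists. Positions further inside a long gene such as SMAD3 were not searched.

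**Figure D1:**
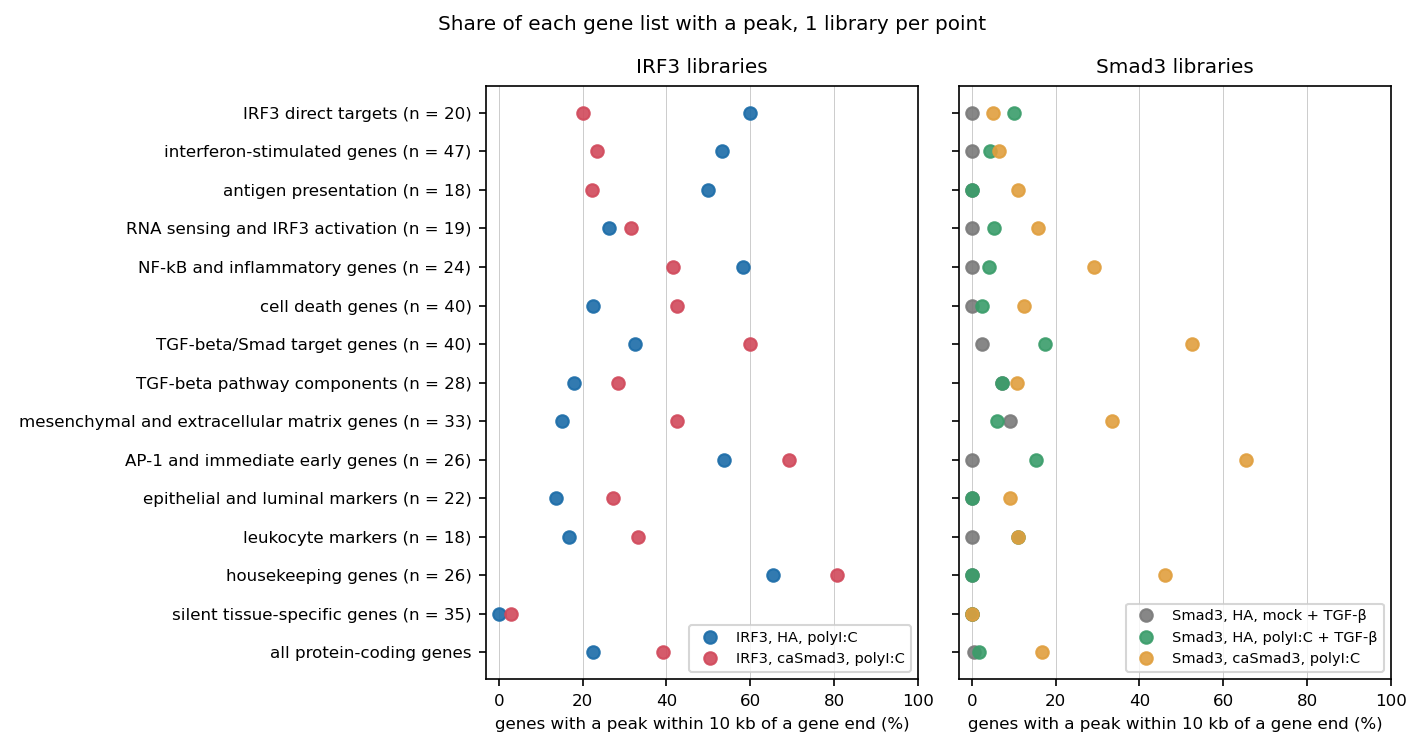
Percent of the genes of each list, and of all protein-coding genes, with a peak within 10 kb of a gene end, with 1 library per point (IRF3 on the left, Smad3 on the right; n is the number of genes in the list). The share of direct IRF3 targets was 60% in HA cells and 20% in caSmad3 cells, while that of all genes was 22.5% and 39.1%.

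Against all other protein-coding genes, the direct targets were enriched in HA cells (60% against 22.5%, Fisher's exact test, adjusted p = 0.0023), as were interferon-stimulated genes (53.2%, adjusted p = 6.3e-05), antigen presentation genes (50.0%, adjusted p = 0.037), NF-kB genes (58.3%, adjusted p = 0.0014), AP-1 genes (53.8%, adjusted p = 0.0029) and housekeeping genes (65.4%, adjusted p = 6.2e-05). Silent tissue-specific genes were depleted, with 0 of 35, where 3 counts would make 8.57% (Fisher's exact test, adjusted p = 0.0023). In caSmad3 cells none of the 3 interferon-related lists passed the exact test (20%, 23.4% and 22.2% against 39.2% of other genes, adjusted p = 0.28, 0.12 and 0.36), and NF-kB genes did not either (41.7%, adjusted p = 1.0). Enrichment by the exact test was found there for TGF-beta/Smad targets (60%, adjusted p = 0.037), AP-1 genes (69.2%, adjusted p = 0.010) and housekeeping genes (80.8%, adjusted p = 2.0e-04), and depletion for silent genes (1 of 35, adjusted p = 1.9e-05). The exact test takes neighbouring genes as independent, and when whole lists were rotated along the gene order the calls of antigen presentation genes in HA cells (adjusted p = 0.24) and of Smad targets in caSmad3 cells (adjusted p = 0.061) were lost. The Smad-target call was also lost with windows of 1 kb (exact test, adjusted p = 0.17) and 50 kb (0.29) and in the wider 50% of peaks (40%, adjusted p = 0.15). The 50 kb window also ended the calls of antigen presentation, NF-kB, AP-1 and silent genes in HA cells and of AP-1 genes in caSmad3 cells, and the wider 50% of peaks those of NF-kB and silent genes in HA cells. A background of genes with a peak in any library is chosen by the same peaks, so that a list that enters it mainly through HA peaks is bound to be low in caSmad3 cells, and its shares test no depletion there. With it the HA calls of direct targets (exact test, adjusted p = 0.064), antigen presentation (0.40), NF-kB (0.12), AP-1 (0.38), housekeeping (0.080) and silent genes (0.99) and the caSmad3 calls of AP-1 and housekeeping genes (1.0 in both) were lost, and Smad targets (77.4%, 0.12) lay below other genes in caSmad3 cells, where 1 silent gene was left and had a peak. Within 1 kb, interferon-stimulated genes, epithelial markers and leukocyte markers were below other genes in caSmad3 cells (exact test, adjusted p = 0.023, 0.019 and 0.0081), as were interferon-stimulated genes in the wider 50% of peaks (adjusted p = 0.032). Epithelial and luminal markers (3 and 6 of 22) and leukocyte markers (3 and 6 of 18) passed in neither library at 10 kb.

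Taken peak by peak, 3415 of the 4125 IRF3 peaks of HA cells overlapped a peak of caSmad3 cells by at least 1 base (82.8%, 81.6 to 83.9), and 49.1% did so over 50% of both peaks. Copies of the list moved to random places of the same chromosome and gene-end class gave a mean of 139.9 and at most 178 (p = 0.001, the smallest that 1000 moved copies can give, one-sided permutation). The 710 HA-only peaks were narrower than the shared ones (median 138 against 199 bases) and less often at gene ends (45.4% against 81.4%), and 4770 peaks were listed in caSmad3 cells alone. Near genes of the 3 interferon-related lists, 13 of 76 HA peaks were shared (17.1%, 9.44 to 27.5), against 84.0% of the 4049 others. Within 50 kb the share was 27 of 97 (27.8%), against 84.1% of the others. Among 10000 width-matched draws of 76 other HA peaks the median was 88.2% and the lowest 72.4%. By gene, 46 of 85 members had an HA peak, and for 34 of them no HA peak was shared. For direct targets 3 of 43 peaks were shared (6.98%), for interferon-stimulated genes 8 of 27 (29.6%), for antigen presentation genes 2 of 8 (25%) and for NF-kB genes 12 of 24 (50.0%), where 0 of 10000 draws fell as low for any of these lists. At TGF-beta/Smad targets 21 of 26 were shared (80.8%) and at housekeeping genes 20 of 22 (90.9%). These draws compare peaks within 1 pair of libraries and are no test of the effect of caSmad3. They take neighbouring peaks as independent, although 22 of the 43 peaks at direct targets lie in the IFIT cluster. Without that cluster, 13 of 54 peaks near the 3 interferon-related lists were shared (24.1%), and 0 of 10000 draws fell as low.

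**Figure D2:**
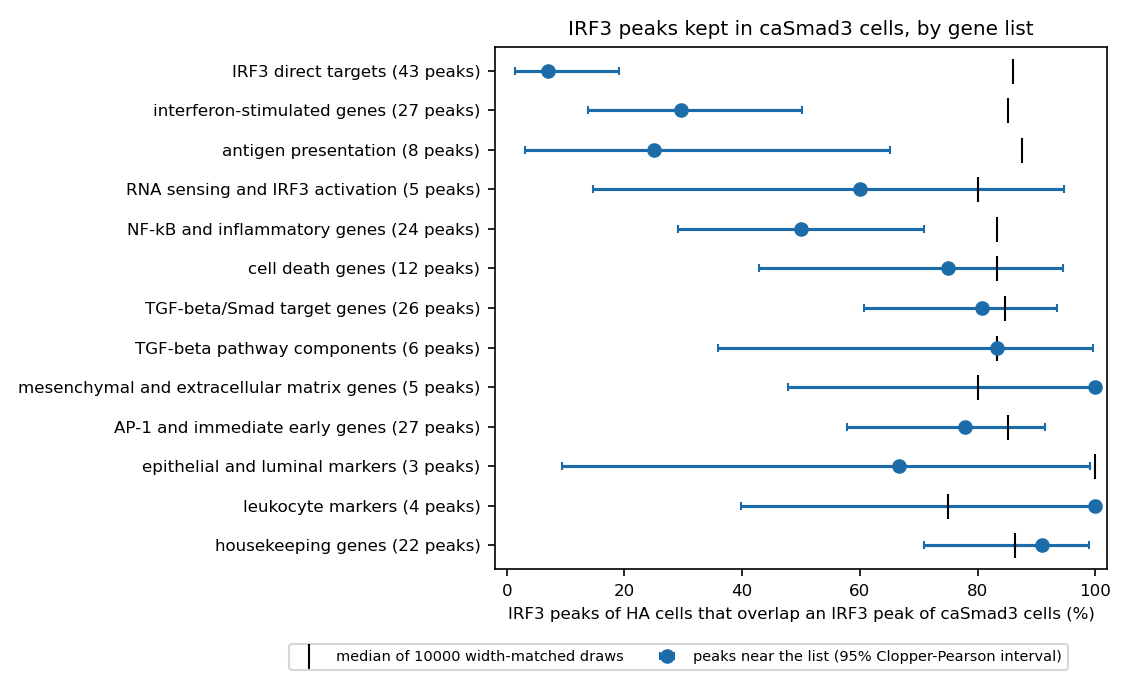
Percent of IRF3 peaks of HA cells, within 10 kb of the genes of each list, that overlapped an IRF3 peak of caSmad3 cells, with 95% Clopper-Pearson intervals; black ticks give the median of 10000 width-matched draws of other peaks. Direct IRF3 targets lie at 6.98% and housekeeping genes at 90.9%, and lists with few peaks have wide intervals. Of the 43 peaks at direct targets, 22 lie in the IFIT cluster, and the intervals and draws take such neighbours as independent.

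**Figure D3:**
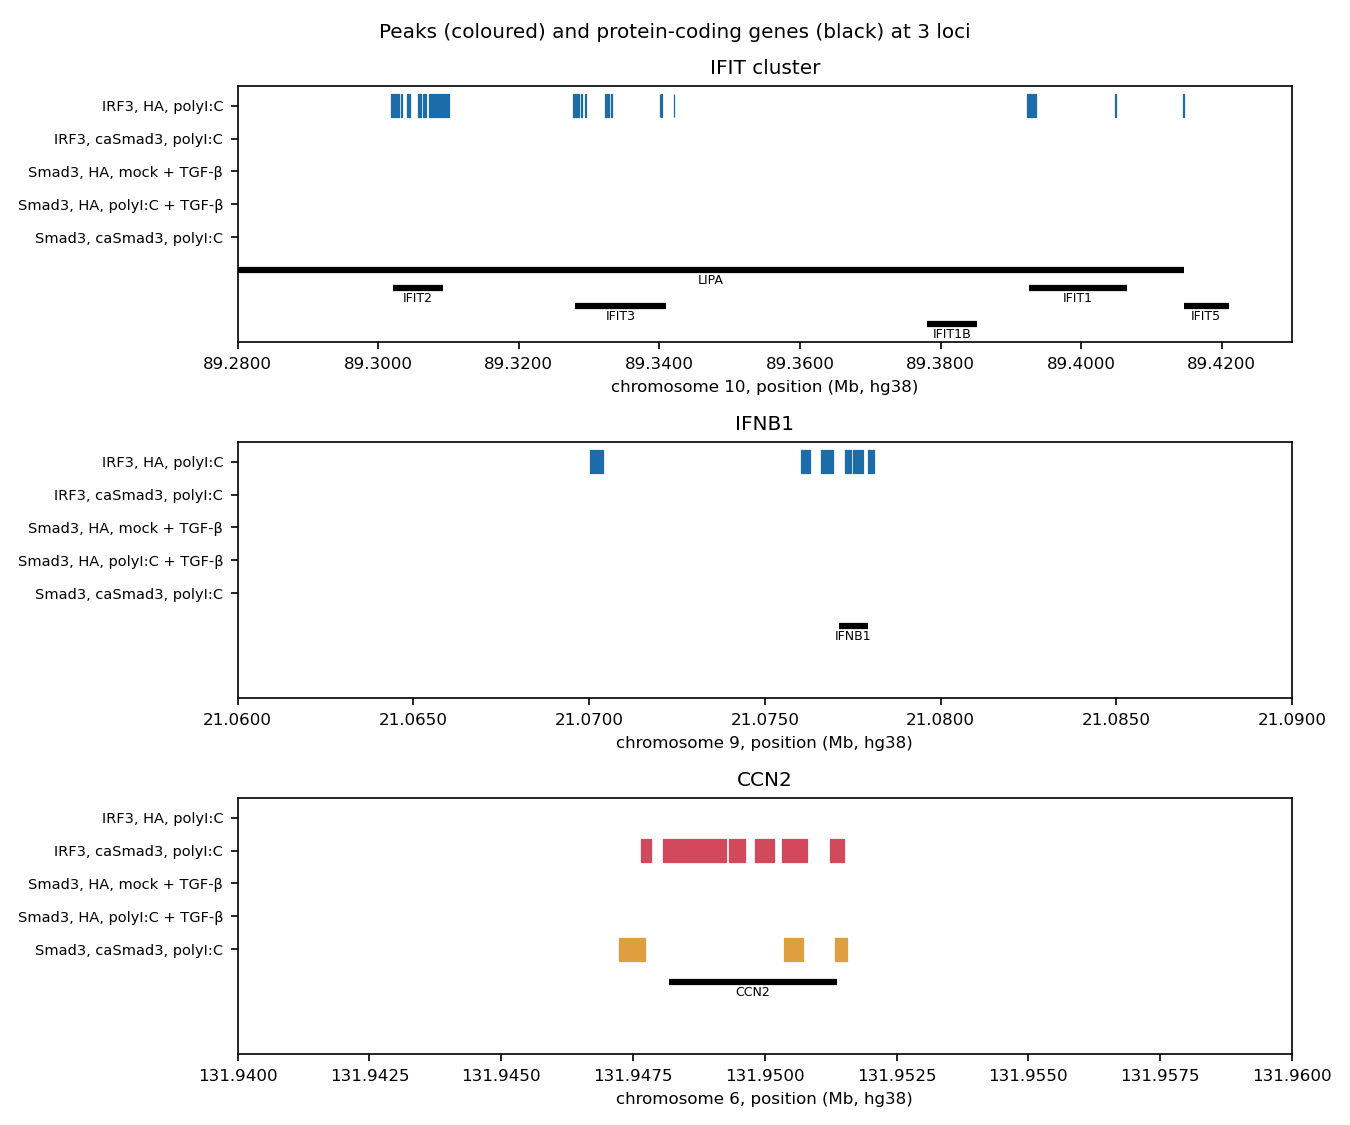
Peaks of the 5 libraries (coloured bars) and protein-coding genes (black bars) along hg38 positions in Mb at the IFIT cluster, IFNB1 and CCN2; bars carry a thin outline so that narrow peaks stay visible. The IFIT cluster holds 22 IRF3 peaks of HA cells and 0 of caSmad3 cells, IFNB1 6 and 0, and CCN2 0 and 6, with 3 Smad3 peaks of caSmad3 cells at CCN2. Peaks in a run along a gene need not be separate sites.

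The next comparison concerned Smad3 in HA cells given TGF-beta, with mock transfection or polyI:C. ID1 and ID3, inhibitors of differentiation induced by TGF-beta family ligands, had Smad3 peaks in both libraries, as did LTBP2, COL1A1 and PLAU. Peaks near further TGF-beta targets (CCN1, GADD45B, JUNB and TGFBI) and near JUN, FOS, IER2 and IER3 were listed after polyI:C and not after mock transfection. ISG15 had a Smad3 peak of 355 bases (chromosome 1, 1013427 to 1013781) after polyI:C alone, inside the span of the IRF3 peak of HA cells. SMAD7, a widely used TGF-beta/Smad3 target, had no Smad3 peak within 10 kb of a gene end in either library.

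Of all protein-coding genes, 118 had a Smad3 peak after mock transfection (0.589%) and 361 after polyI:C (1.80%). By list, TGF-beta/Smad targets counted 1 of 40 after mock transfection (2.5%, adjusted p = 0.46, Fisher's exact test) and 7 after polyI:C (17.5% against 1.77% of other genes, adjusted p = 7.6e-05). Within 50 kb the mock library passed as well (10.0%, exact test, adjusted p = 0.042), and the difference between the libraries was not tested. AP-1 genes counted 0 of 26, where 3 counts would make 11.5%, and 4 (15.4%, exact test, adjusted p = 0.0057). Mesenchymal and matrix genes counted 3 of 33 (9.09%, exact test, adjusted p = 0.0051) and 2 (adjusted p = 0.30), and the first call was lost with windows of 1 kb (adjusted p = 0.20) and 50 kb (0.11) and in the wider 50% of peaks (3.03%, 0.25). Within 50 kb it was the polyI:C library that passed (18.2%, exact test, adjusted p = 0.035). At 10 kb the libraries shared COL1A1 and PLAU, and VIM was in the mock list alone. TGF-beta pathway components counted 2 of 28 in each, ID1 and ID3 (exact test, adjusted p = 0.043 and 0.25), and the first call was lost at 50 kb (0.28) and with rotated lists (0.094). Lists that passed in neither library were direct IRF3 targets (0 and 2 of 20, the latter ISG15 and ISG20), interferon-stimulated genes (0 and 2 of 47, IRF2 and PLSCR1), NF-kB genes (0 and 1 of 24, CXCL1), cell death genes (0 and 1 of 40, MCL1), RNA sensing genes (0 and 1 of 19) and leukocyte markers (0 and 2 of 18). Antigen presentation, epithelial, housekeeping and silent genes had 0 in both, where 3 counts would make 16.7%, 13.6%, 11.5% and 8.57%. For the other lists that passed in neither library, 3 counts would make 6.38% to 16.7% in place of the 0 after mock transfection. None of these counts of 0 was evidence of depletion.

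Of the 353 Smad3 peaks after mock transfection, 247 overlapped a peak after polyI:C (70.0%, 64.9 to 74.7), against a mean of 0.178 and at most 2 for moved copies (p = 0.001, the smallest possible with 1000 copies, one-sided permutation). The 106 mock-only peaks had a median width of 114 bases and the shared ones 206, and 548 peaks were listed after polyI:C alone. The 3 widest shared peaks lay on rRNA gene copies of chromosome 21. The widest mock-only peak lay 810 bases below ID1 (chromosome 20, 31604104 to 31604479), near 4 peaks listed within 10 kb of ID1 after polyI:C. The widest polyI:C-only peaks were at an snRNA gene (563 bases), at the histone gene H4C15 (526 bases) and at a site 30508 bases from an end of TNFRSF10B (482 bases, chromosome 8, 22989385 to 22989866), which encodes a TRAIL receptor.

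A further comparison set Smad3 in HA cells given polyI:C and TGF-beta beside Smad3 in caSmad3 cells given polyI:C without TGF-beta, so that active Smad3 and the absence of TGF-beta cannot be separated. Smad3 peaks lay near 21 of 40 TGF-beta/Smad targets in caSmad3 cells and near 7 in HA cells, and the 21 included all 7. Among all protein-coding genes 3362 had a Smad3 peak in caSmad3 cells (16.8%) and 361 in HA cells (1.80%), a larger ratio than in this list, and 337 of the 361 were in both. CCN2, BHLHE40, PMEPA1 and ADAM12 were among the 14 listed in caSmad3 cells alone, and so was SMAD7, with 2 peaks. LTBP2, CCN1, GADD45B and JUNB had peaks in both. Mesenchymal and matrix genes counted 11 of 33 against 2, with COL7A1, VIM, ITGB1 and PLAUR in caSmad3 cells alone of these libraries. VIM also had a Smad3 peak in mock-transfected HA cells. AP-1 genes counted 17 of 26 against 4, with DUSP1, MYC, EGR1 and SGK1 in caSmad3 cells alone.

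Among genes of the lists the widest Smad3 peak lay near COL1A1, with 948 bases in caSmad3 cells (chromosome 17, 50177956 to 50178903), 265 in HA cells given polyI:C and 452 after mock transfection, all more than 5 kb below the gene. PDCD1LG2, which encodes the checkpoint ligand PD-L2, had a peak of 907 bases 84 bases below the gene (chromosome 9, 5509541 to 5510447) in caSmad3 cells alone. In the other direction, the Smad3 peak at ISG15 was absent from the caSmad3 list, as were those at ISG20, IRF2 and PLSCR1. At SMAD7 the widest peak lay 1748 bases above the gene (chromosome 18, 48952713 to 48952888).

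In caSmad3 cells, 52.5% of TGF-beta/Smad targets (adjusted p = 8.6e-06, Fisher's exact test), 65.4% of AP-1 genes (adjusted p = 3.0e-06) and 46.2% of housekeeping genes (12 of 26, adjusted p = 0.0029) had a Smad3 peak, against 16.7% of other genes in each case. Silent genes were depleted (0 of 35, where 3 counts would make 8.57%, exact test, adjusted p = 0.011). Mesenchymal and matrix genes missed the threshold (33.3%, exact test, adjusted p = 0.062) and passed it within 1 kb (27.3%, 0.022). The wider 50% of peaks and the background of genes with a peak in any library ended the calls of housekeeping and silent genes, as did 50 kb for housekeeping and 1 kb for silent genes. Lists that did not pass were direct IRF3 targets (1 of 20, TNFSF10), interferon-stimulated genes (3 of 47, among them IFI35 and TRIM25), antigen presentation (2 of 18, PDCD1LG2 and TAPBP), NF-kB genes (7 of 24), cell death genes (5 of 40), RNA sensing (3 of 19), pathway components (3 of 28), epithelial markers (2 of 22) and leukocyte markers (2 of 18).

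By position, 679 of the 786 Smad3 peaks of HA cells given polyI:C overlapped one of caSmad3 cells (86.4%, 83.8 to 88.7), and 324 of the 353 after mock transfection did (91.8%, 88.4 to 94.4). For the polyI:C list the share was 39.9% over 50% of both peaks, and 49.7% with equal numbers of the widest peaks. Moved copies gave at most 9 and 7 (p = 0.001 in both, the smallest possible with 1000 copies, one-sided permutation). A further 5391 peaks were listed in caSmad3 cells alone. The widest of the 107 peaks without a counterpart were at ISG15, at a site 29219 bases from an end of GRHL3 and at a site 19932 bases from an end of SHLD1.

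The last comparison set the antibodies side by side in caSmad3 cells given polyI:C. Peaks of both antibodies lay near CCN2, CCN1, LTBP2 and GADD45B among Smad targets, near COL1A1, VIM, THBS1 and LOXL2 among matrix genes, near JUN, SGK1, IER2 and DUSP6, and near ID1, ID2 and ID3. At LTBP2, COL1A1 and VIM the peaks of the antibodies did not overlap. At LTBP2 the IRF3 peak lay 4207 bases below the gene (chromosome 14, 74493787 to 74493976) and the widest Smad3 peak 5828 bases above it (74618065 to 74618849). Of the 21 TGF-beta/Smad targets with a Smad3 peak, 16 also had an IRF3 peak (76.2%), against 2730 of all 3362 protein-coding genes with a Smad3 peak (81.2%). Peaks of the antibodies overlapped at 9 of the 16. The other 5 of the 21 included SMAD7, ITGB6 and TGFBI. AP-1 genes gave 15 of 17, with overlap at 14, housekeeping genes 12 of 12, with overlap at 11, and matrix genes 10 of 11, with overlap at 6. Direct IRF3 targets gave 0 of 1, with IRF3 peaks and no Smad3 peak at ISG15, PMAIP1, ZC3HAV1 and NCOA7.

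Of the 6041 Smad3 peaks, 1909 overlapped an IRF3 peak of the same cells (31.6%, 30.4 to 32.8), and 11.7% did so over 50% of both peaks. At the 1-base overlap moved copies gave a mean of 91.7 and at most 119 (p = 0.001, the smallest possible with 1000 copies, one-sided permutation). As the copies were not confined to accessible chromatin, this value cannot tell joint binding from peaks at the same open sites. Gene ends held 73.8% of these shared peaks (71.8 to 75.8) and 14.3% of the 4132 with Smad3 alone (13.3 to 15.4). The widest shared peak lay at VMP1 (1952 bases, chromosome 17, 59842579 to 59844530). The widest with Smad3 alone lay 12538 bases from an end of SLC25A37 (1307 bases, chromosome 8, 23540842 to 23542148), and the widest with IRF3 alone were at CCN2, SERBP1 and SF3A2. In HA cells, where the Smad3 library had received TGF-beta and the IRF3 library had not, 245 of 786 Smad3 peaks overlapped an IRF3 peak (31.2%, 27.9 to 34.5). Of those 245, 132 lay at genes of structural RNAs or histones, and without such sites the share was 17.4% of 650 (14.6 to 20.5).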

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

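The tests at structural RNA genes and of peak width were set before their results were seen. Peaks at genes of rRNA, snRNA, tRNA, snoRNA, other small RNAs and histones stood out because these genes belong to none of the 14 gene lists and still held many of the peaks. Their peaks were part of the overlap comparisons, where they made up 243 of the 3415 shared IRF3 peaks of HA cells and 87 of the 247 shared Smad3 peaks after mock transfection. They took 6.13% of the IRF3 peaks of HA cells, 3.81% of those of caSmad3 cells, 25.5% of the Smad3 peaks after mock transfection, 17.3% of those after polyI:C and 4.70% of those of caSmad3 cells. Among the 20 widest peaks of these lists they numbered 17, 20, 18, 17 and 14.

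Recovery of such loci with either antibody is a candidate explanation. At these genes 85.6% of the Smad3 peaks of caSmad3 cells overlapped an IRF3 peak of the same cells (80.9 to 89.4), against 28.9% elsewhere (27.8 to 30.1). In HA cells the shares were 98.9% against 16.7% after mock transfection and 97.1% against 17.4% after polyI:C. Both Smad3 lists, made with TGF-beta, were set against the IRF3 list of HA cells given polyI:C without TGF-beta. An IRF3 library of mock-transfected cells is not in the series. Real binding of both factors to highly transcribed genes would give the same values and stays open, since an input or IgG library was not analysed here.

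The small number of Smad3 peaks in HA cells beside the 6041 of caSmad3 cells may reflect lower sensitivity of the HA libraries. Peaks of caSmad3 cells that were also in the polyI:C list had a median width of 399 bases, at percentile 89.3 of the caSmad3 list, and those also in the mock list 469 bases, at percentile 93.2. Stronger binding of active Smad3 would also add narrow peaks, so that a biological difference stays open and untested.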

How the results depend on the processing

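Alternatives by peak width, without structural RNA and histone genes, without the IFIT cluster and with rotated lists were chosen after seeing the data. The settings planned by peak score, like those for motifs, were not run. No paired analysis was possible because each group has 1 library. Of 489 recomputed values, 423 kept their side of the threshold, stayed within their interval or, for peak numbers, stayed within a set fold change. For gene lists a change of direction was counted only where the main or the alternative value passed the threshold. The 4 overlap results stayed past the threshold under each alternative, each time against moved copies not confined to accessible chromatin. At 50% reciprocal overlap the shares were 49.1% for IRF3 in HA against caSmad3 cells, 52.1% for Smad3 after mock against polyI:C, 39.9% for Smad3 in HA against caSmad3 cells and 11.7% for Smad3 against IRF3 in caSmad3 cells. Interferon-related HA peaks shared with caSmad3 cells were 24.1% without the IFIT cluster and 27.8% within 50 kb. In the order IRF3 in HA and caSmad3 cells, then Smad3 after mock, after polyI:C and in caSmad3 cells, peaks of at least 200 bases numbered 1891, 4400, 140, 273 and 2610, and peaks at ends of all genes made 84.2%, 85.7%, 41.1%, 41.2% and 42.7%. Within 2.5 kb the gene-end share was 78.5%, 80.4%, 25.1% and 37.9%, leaving out mock, which stayed within its interval. Without structural RNA and histone genes it was 77.1% and 78.2% for IRF3 and 18.0% for Smad3 after polyI:C, and in the wider 50% of peaks 81.4% for IRF3 and 30.5% for Smad3 in caSmad3 cells.

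Of 420 values for gene lists, 374 kept their side. Of the rest, 31 lost a call, 12 gained one and 3 reversed direction. Most of the 70 tests had not passed at the main setting, so the 374 say little about how stable the calls are. Rotating the lists along the gene order, which keeps neighbouring members together, ended 3 calls and left the shares as they were, for IRF3 at antigen presentation genes in HA cells (50.0%) and at Smad targets in caSmad3 cells (60%) and for Smad3 after mock at pathway components (7.14%). Within 1 kb, 4 calls were gained in caSmad3 cells, as IRF3 lay below other genes at interferon-stimulated (12.8%), epithelial (4.55%) and leukocyte genes (0.0%) and Smad3 lay above them at matrix genes (27.3%). Calls were lost for IRF3 in caSmad3 cells at Smad targets (45.0%), for Smad3 after mock at matrix genes (3.03%) and for Smad3 in caSmad3 cells at silent genes (0.0%). Within 50 kb, Smad3 gained Smad targets after mock (10.0%) and matrix genes after polyI:C (18.2%). That window ended calls for IRF3 in HA cells at antigen presentation (55.6%), NF-kB (62.5%), AP-1 (61.5%) and silent genes (20%), for IRF3 in caSmad3 cells at Smad targets (70.0%) and AP-1 genes (73.1%), for Smad3 after mock at pathway components (7.14%) and matrix genes (9.09%), and for Smad3 in caSmad3 cells at housekeeping genes (53.8%). In the wider 50% of peaks, depletion of interferon-stimulated genes was gained for IRF3 in caSmad3 cells (8.51%). Lost there were NF-kB (29.2%) and silent genes (0.0%) for IRF3 in HA cells, Smad targets (40%) for IRF3 in caSmad3 cells, matrix genes after mock (3.03%), and housekeeping (23.1%) and silent genes (0.0%) for Smad3 in caSmad3 cells. The cause of these shifts was not tested.

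A background of genes with a peak in any library compares fewer genes, most of them bound by IRF3, and is chosen by the peaks that are tested. The interferon-related lists enter it mainly through HA cells, with 12, 25 and 9 members bound by IRF3 there and 4, 11 and 4 in caSmad3 cells, so that its low shares in caSmad3 cells follow from the choice and are no evidence of depletion. It ended calls for IRF3 in HA cells at direct targets (85.7%), antigen presentation (75%), NF-kB (77.8%), AP-1 (70.0%), housekeeping (77.3%) and silent genes (0.0%), for IRF3 in caSmad3 cells at AP-1 (90.0%) and housekeeping genes (95.5%), and for Smad3 in caSmad3 cells at housekeeping (54.5%) and silent genes (0.0%). The low shares past the threshold were those for IRF3 in caSmad3 cells at direct targets (28.6%), interferon-stimulated (40.7%) and antigen presentation genes (33.3%) and for Smad3 there at interferon-stimulated genes (11.1%). Smad3 there was above other genes at matrix genes (73.3%). Direction reversed for IRF3 in caSmad3 cells at NF-kB genes (55.6%, below other genes), Smad targets (77.4%, below) and silent genes (100%, a single gene).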

Other observations

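The test of NF-kB peaks was chosen after the other results of this part were seen, and the genes outside the lists were chosen after their values were seen. Several wide IRF3 peaks of HA cells without a counterpart in caSmad3 cells lay at genes outside the 14 lists. The widest within 1 kb of a gene end were at WARS1 (697 bases, chromosome 14, 100375197 to 100375893), ZFP36 (542 bases, chromosome 19, 39408712 to 39409253), DDX60L (503 bases, chromosome 4, 168480189 to 168480691), HERC6 (434 bases, chromosome 4, 88379163 to 88379596) and APOL6 (423 bases, chromosome 22, 35648161 to 35648583). These 5 are the widest of 27 such peaks, more than 10 kb from any gene of the lists, among the 60 widest HA-only peaks at gene ends, and the others lay at genes as different as STK24, HIP1R, KAT6A and YME1L1, so no theme was tested. WARS1 encodes a tryptophanyl-tRNA synthetase, and ZFP36 an RNA-binding protein that destabilises cytokine transcripts. Of the 100 widest HA-only peaks, 27 lay within 10 kb of a gene of the interferon-related lists (18.6 to 36.8%), and of the 100 widest caSmad3-only peaks 0 did, where 3 counts would make 3.0%. Of the former, 61 lay neither near these lists nor at a gene end. At gene ends lay 33 of the former and 84 of the latter.

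The low share of interferon-related IRF3 peaks in caSmad3 cells was weighed against technical explanations. Lower sensitivity of the caSmad3 library, if alike at all peaks of one width, would leave these peaks as often shared as others. Instead 17.1% were shared, below all 10000 width-matched draws. The draws were matched by width alone and took neighbouring peaks as independent. They cannot exclude a poorer IRF3 precipitation that lost IRF3 sites and kept peaks recovered with either antibody. Narrow peaks near the calling threshold are argued against by the wider 50% of HA peaks, where 23.5% of those near the lists were shared and 91.8% of the others. Smad3 taking over the same sites would place Smad3 peaks there. Of the 63 unshared peaks, 0 overlapped a Smad3 peak of caSmad3 cells (0.0%, 0.0 to 5.69), where 3 counts would make 4.76%. The interval takes neighbouring peaks as independent. The share was 9.72% for all 710 HA-only peaks (7.64 to 12.1) and 35.1% for all shared HA peaks. A weaker polyI:C response of the caSmad3 culture as a whole may account for the pattern. NF-kB and inflammatory genes also had few shared peaks (50.0%, matched median 83.3%). These are IRF3 peaks too, so an effect of caSmad3 on IRF3 would give the same value, which cannot tell the explanations apart. With 1 library per group neither a weaker response nor an effect of caSmad3 on IRF3 can be excluded.

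Chromosomes differed in peaks per 100 protein-coding genes with both antibodies. In caSmad3 cells Smad3 had 69.1 on chromosome 20, 62.2 on chromosome 9, 54.5 on chromosome 3 and 54.1 on chromosome 8, against 11.2 on chromosome 11 and 14.5 on X. IRF3 in the same cells had 57.9, 56.0, 51.2 and 44.5 on the first 4 of these and 29.8 on X, and its lowest value was also on chromosome 11. Its highest value was 59.0 on chromosome 21, where Smad3 had 33.9, and it had 54.7 on chromosome 14, where Smad3 had 46.3. The values of chromosome 21 include peaks on its rRNA gene copies, which are not among the protein-coding genes. Over all chromosomes, 70 IRF3 peaks and 48 Smad3 peaks of caSmad3 cells lay at rRNA genes. DNA copy number was not analysed here.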
